A study of Mus musculus with 16 samples.

How the data were processed

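The series profiled the histone mark H3K27me3, a repressive mark written by the Polycomb enzyme EZH2, in CCN6KOT cells, which are mouse breast tumour cells from a CCN6 knockout model. Per the labels' protocols, the cells were transduced with a control lentivirus (PPGS in the labels) or with a lentivirus carrying dnTCF4, a dominant negative form of the transcription factor through which beta-catenin acts, and were then selected with puromycin. Per the labels' protocols, chromatin fixed in 1% formaldehyde was sheared and immunoprecipitated with 4 micrograms of antibody, and libraries were made by ChIPmentation, in which a transposase adds the sequencing adapters on the beads. The 16 samples comprise 4 control and 4 dnTCF4 libraries for H3K27me3, and 8 IgG libraries, whose data were not analysed here. The labels number the libraries of each group 1 to 4 and do not say whether these came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

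Per the submitters' processing notes, the tools were Trim Galore, cutadapt, Bowtie2 2.3.4.1, Picard 2.20.2, SAMtools 1.2, bedtools 2.28.0 and MACS2 2.1.2, with the mouse build mm10. Their options, and whether IgG served as the control of the peak caller, are not given in the sources used here. The deposited values used here are 1 peak list per H3K27me3 library, with 9 columns and no header, and the peak names in each list carry that library's name, so peaks were called per library and not on pooled samples. The deposited score of each peak equalled 10 times its −log10 q truncated to a whole number, except for 7 of 106385 peaks. The deposited lists also hold a fold enrichment over background, which is the authors' ratio per peak, and a −log10 p and −log10 q value per peak. The lowest deposited −log10 q was 1.01. These columns are the authors' own values per peak and were used only to describe, rank or filter peaks within a list, and to estimate the background behind each peak under the Poisson model of MACS2. A peak list holds no read counts, so the sequencing depth of each library is unknown, a missing peak does not show a missing mark, and the number of peaks reflects both the mark and how much each library could detect. All peaks lay on the 19 autosomes and X.

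Gene positions came from the RefSeq annotation of the same build (GRCm38.p6), with 21631 protein-coding genes on the autosomes and X. That table gives gene starts and ends without strand. The design fixed before the data were examined called for windows around transcription start sites, which cannot be placed without strand. It would have dropped promoter and gene list results had a suitable annotation been missing. As a departure from that design, the windows were placed around both annotated ends of each gene, 2 kb to each side. A gene counted as marked when a peak overlapped either window by at least 1 base. A mark at a gene's far end is therefore counted like a mark at its promoter, and only the outermost ends of each gene were used. These windows hold 5.62% of the annotated length, taken as the sum of the last gene ends of the chromosomes (2631 Mb). All members of the 20 gene lists matched the annotation, 531 distinct genes in all.

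Peak number, covered length, median peak width and the share of marked genes were compared on the log10 scale, and within-library shares on the percent scale. Each was tested with a two-sided exact permutation test of the difference of group means over the 70 assignments of 8 libraries to 4 and 4, whose smallest p is 0.0286. For each gene list and library, the log2 odds ratio of a marked gene against all other protein-coding genes was computed with 0.5 added to each cell, tested in the same way, and adjusted by the Benjamini-Hochberg method over the 20 lists. The added 0.5 pulls odds ratios of short peak lists upwards, because a gene list with no marked member in a library still has a ratio, which is higher the fewer genes that library marks. Within a library, Fisher's exact test compared each list with other genes, adjusted over the 160 combinations of list and library. It describes that library only, and it treats neighbouring genes as independent. Confidence intervals of shares are 95% Wilson intervals and cover counting error only. Genes and regions marked in a single group had a peak in at least 2 of 4 libraries of that group and 0 of the other, and single genes were tested with Fisher's exact test. Regions were the union of all 8 lists merged where peaks overlapped. Libraries were compared by the Jaccard index of covered bases and by the overlap coefficient (shared bases over the shorter covered length), with a one-sided exact permutation test of the within-group minus the between-group mean.

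The genes named follow a rule fixed together with that design. They are the 21 genes tied to the study, the 10 genes marked in the most libraries, the 10 with the largest difference in number of libraries in each direction, up to 4 members per list with a peak in the most libraries, and the 5 regions with the largest difference in each direction. Ties were broken by the covered share of the window, and for regions by length. Other genes, clusters and chromosomes named were chosen after their values were seen. A gene that the rule takes is not reported here. Alternatives were leaving out each library, a stricter minimum of −log10 q (1.43, the median over all peaks), windows of 1 kb and 5 kb, a window covered to at least 50%, lists reduced to their 191 highest peaks, only libraries with at least 1000 peaks, fixed 10 kb bins, a stricter rule of 3 libraries, a conditional exact test given each library's total, and same-numbered libraries taken as pairs. Further alternatives, such as whole genes extended by 2 kb and leaving out a block of chromosome 9, were chosen after seeing the data.

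The methods were tested on simulated data. For genes marked in a single group, presence was simulated for 21631 genes with the real library totals, and 200 genes were set as marked in most control libraries, short lists included, and in no dnTCF4 library. The rule of 2 against 0 libraries found 99.5% of those 200 genes and also 334 others. Fisher's exact test gave 61.5% of them an unadjusted p under 0.05 and none an adjusted p under 0.05, and the conditional test gave none an adjusted p under 0.05, so single genes with such a change were not called after adjustment. With no change simulated, the rule still found 339 genes in the control direction and 55 in the dnTCF4 direction. For gene lists, in 100 simulated draws over 21631 genes, a list of 100 genes drawn from those marked most readily, with 16-fold higher odds in the dnTCF4 libraries had an unadjusted p under 0.05 in 99% of draws and an unchanged list in 2% (exact permutation test). The alternative test of observed over expected members found the changed list in 7% of draws. Smaller changes and shorter lists were not simulated. The real lists held 6 to 98 genes, several with few marked members, so the 99% does not carry over to them. Covered bases equalled a base-by-base count in all of 500 random windows on chromosome 9 in dnTCF4 2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.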

Results

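H3K27me3 was mapped in CCN6KOT mouse breast tumour cells carrying a control lentivirus or dnTCF4, with 4 libraries of each group. The comparison asks how blocking beta-catenin/TCF activity bears on the mark that EZH2 writes. The 4 control libraries held 426, 738, 54070 and 22745 peaks, and the 4 dnTCF4 libraries 21492, 191, 4885 and 1838, in the order of their numbers. Peaks covered between 0.129 Mb (dnTCF4 2) and 52.7 Mb (control 3). Sequencing depth is unknown, and the IgG libraries were not analysed here.

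**Figure D1:**
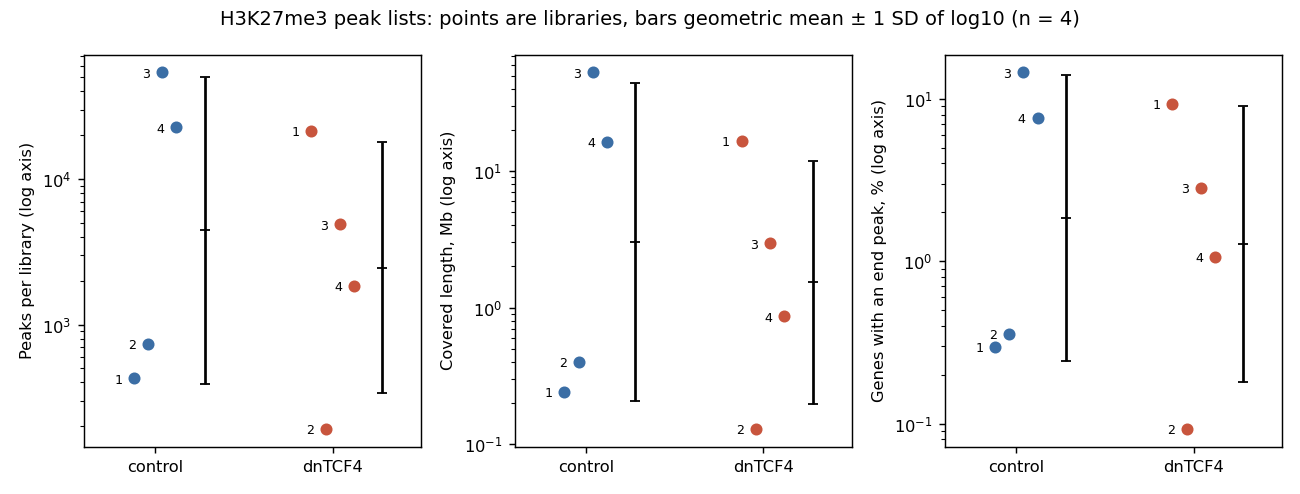
Peaks, covered length in Mb and the share of protein-coding genes with an end peak, each on a log axis, for control (blue) and dnTCF4 (red) libraries. Points are libraries with their numbers, and bars show the geometric mean and 1 SD of log10 values (n = 4). Libraries of a group lie far apart, from 426 to 54070 peaks in control and from 191 to 21492 in dnTCF4.

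H3K27me3 peaks lay at developmental and epithelial genes in both groups and at none of 40 ribosomal protein and housekeeping genes. Of 39 Hox genes, which set position along the body axis, 26 were marked in control 3, 21 in control 4 and 25 in dnTCF4 1. Of 98 other developmental transcription factors, 43, 23 and 33 were marked in the same libraries. Pax2 and Six3 were marked in 3 control and 3 dnTCF4 libraries, and Nkx2-5 and Pax1 in 2 control and 3 dnTCF4 libraries. The Hox list was over-represented among marked genes in 7 of 8 libraries by Fisher's exact test, with adjusted p between 9.11e-15 (dnTCF4 1) and 6.53e-05 (control 1). The exception, dnTCF4 2, had 20 marked genes and no Hox gene among them. The other developmental transcription factors were over-represented in 4 libraries, namely control 3, control 4, dnTCF4 1 and dnTCF4 3. The housekeeping list was under-represented in control 3, with 0 of 40 genes marked where 14.5% of all genes were (Fisher's exact test, adjusted p = 0.0216).

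The Hox clusters were marked unevenly. All 9 Hoxc genes on chromosome 15 were marked in control 3, control 4, dnTCF4 1 and dnTCF4 3, and 7 of 9 in dnTCF4 4. Of the 11 Hoxa genes on chromosome 6, 2 were marked in control 3, 1 in control 4 and 4 in dnTCF4 1. The 10 Hoxb genes on chromosome 11 had 9, 5 and 7 marked in these libraries, and the 9 Hoxd genes on chromosome 2 had 6, 6 and 5. Control 1 and control 2, the shortest control lists, marked 4 and 5 Hox genes, all of them Hoxc, so their over-representation rests on this cluster. Chromosome 15 as a whole held 40.1% and 32.8% of covered length outside a block of chromosome 9 in these libraries, where it makes up 3.95% of annotated length. Hoxc4, Hoxc5 and Hoxc9 were marked in 4 control and 3 dnTCF4 libraries. The division by cluster was chosen after the data were seen.

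Epithelial genes carried peaks more often than mesenchymal genes in both groups. In control 3, 16 of 30 epithelial genes were marked (53.3%, 95% Wilson interval 36.1% to 69.8%), against 2 of 30 mesenchymal genes (6.67%, 1.85% to 21.3%). Control 4 marked 9 and 1, dnTCF4 1 marked 14 and 2, and dnTCF4 3 marked 6 and 0. Fisher's exact test of the lists against each other, chosen after the data were seen and adjusted over 8 libraries, gave p = 0.00116, 0.0325, 0.00364 and 0.0474 for these libraries. The other 4 libraries marked 0 to 2 epithelial genes, with adjusted p from 0.786 to 1. Without control 3, control 4 or dnTCF4 1, or under the stricter minimum or with windows of 1 kb, 2 libraries passed, and 0 passed with lists of equal length or with windows covered to 50%. Epcam, a cell adhesion protein of epithelia, was marked in 3 control and 2 dnTCF4 libraries. Grhl2, a transcription factor of epithelial identity, and Spint1 were marked in 2 control and 3 dnTCF4 libraries. Cdh1, the gene of E-cadherin, was marked in control 3, control 4 and dnTCF4 1. Postn and Thy1 were the mesenchymal genes marked, Postn in 2 control and 1 dnTCF4 library and Thy1 in 1 of each. Vim, Zeb1, Snai1 and Twist1 had no peak at a gene end in any library.

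Among mammary genes, 8 of 22 luminal genes were marked in control 3 and 7 in dnTCF4 1, and the list was over-represented in 5 libraries. Lalba, which encodes the milk protein alpha-lactalbumin, was marked in 3 control and 4 dnTCF4 libraries, and Ehf in 3 of each. Lalba lies on chromosome 15, which makes up 3.95% of annotated length. Outside the block of chromosome 9, chromosome 15 held 40.1% of covered length in control 1 and 27.1% in dnTCF4 2. The basal and myoepithelial list had 5 of 22 genes marked in control 3 and 3 in dnTCF4 1, and passed the test in no library. Krt5, a basal keratin, was marked in 2 control and 0 dnTCF4 libraries. Krt14 was marked in 1 of each.

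Wnt pathway genes were marked in the longer lists of both groups. Of 19 Wnt ligands, 8 were marked in control 3, 3 in control 4, 6 in dnTCF4 1 and 3 in dnTCF4 3. These libraries marked 14.5%, 7.66%, 9.29% and 2.83% of all genes. Wnt8b was marked in 2 libraries of each group and Wnt11 in 2 control and 1 dnTCF4 library. Of 20 secreted or membrane antagonists, the same libraries marked 9, 6, 6 and 3. These included Sost, Frzb and Nkd2, each marked in 2 libraries of both groups, and Dkk1, marked in 2 control and 1 dnTCF4 library. Of 26 beta-catenin/TCF target genes, 9, 6, 6 and 4 were marked. By Fisher's exact test the ligands were over-represented only in control 3 and dnTCF4 1. The antagonists passed in control 3, control 4 and dnTCF4 1, and the targets in control 3, dnTCF4 3 and dnTCF4 4. Mmp7 was marked in all 8 libraries, T in 2 control and 3 dnTCF4 libraries and Ascl2 in 2 of each. Mmp7 lies in a block of chromosome 9 where peaks had low fold enrichment.

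**Figure D2:**
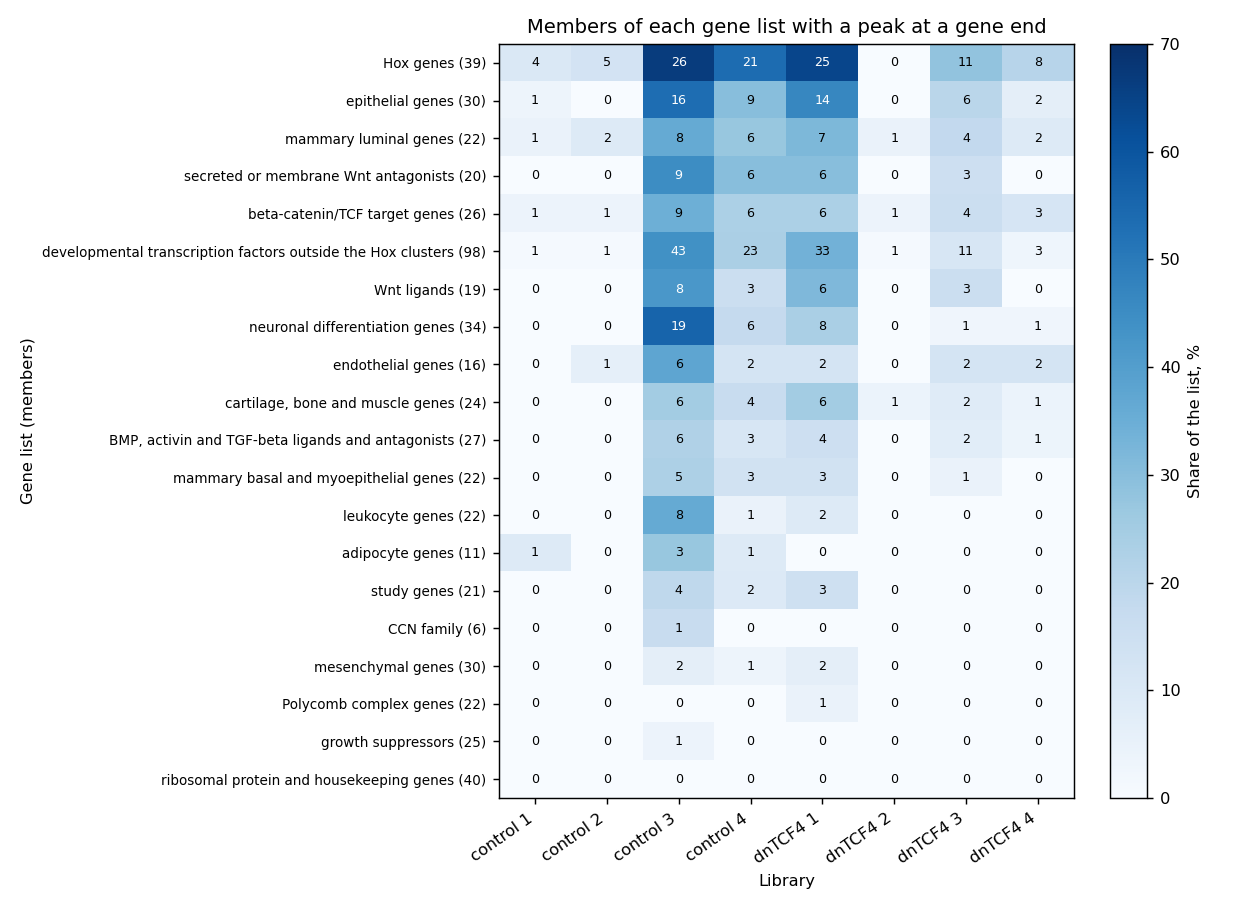
Members of each gene list (rows, with the number of members) that had a peak within 2 kb of a gene end in each library (columns); the colour gives the share of the list in percent and the number the count. The Hox list reached 26 of 39 in control 3 and 25 of 39 in dnTCF4 1, and no housekeeping gene was marked in any library.

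None of the 20 lists passed the test of a difference between control and dnTCF4 libraries relative to all genes, which would have needed at least 12 lists at the smallest possible p of 0.0286. The log2 odds ratio of the Hox genes was 4.61 ± 1.07 in control and 4.09 ± 0.43 in dnTCF4 libraries (SD, n = 4 each; difference -0.52, exact permutation p = 0.371, adjusted p = 0.971). That of the epithelial genes was 2.86 ± 0.86 and 3.36 ± 0.50 (SD, n = 4 each; difference 0.50, exact permutation p = 0.343, adjusted p = 0.971), and that of the beta-catenin/TCF targets 3.00 ± 1.38 and 3.56 ± 1.87 (SD, n = 4 each; difference 0.57, exact permutation p = 0.657, adjusted p = 0.971). In control 1, control 2 and dnTCF4 2 the ratio of the beta-catenin/TCF targets (4.32, 4.05 and 6.02) rested on Mmp7 alone. The Hox ratio of dnTCF4 2 (3.74) rested on the added 0.5, since 0 of 39 Hox genes were marked there. So did the epithelial ratios of control 2 (2.19) and dnTCF4 2 (4.11), with 0 of 30 genes marked. The developmental transcription factors gave 2.16 ± 0.19 and 2.60 ± 1.02 (SD, n = 4 each; difference 0.44, exact permutation p = 0.657, adjusted p = 0.971). No list reached an unadjusted p under 0.05 in this test. With observed over expected members, an alternative chosen after seeing the data, the cartilage, bone and muscle list reached an exact permutation p of 0.0286 (difference 0.70 on the log2 scale, adjusted p = 0.429, where the lowest adjusted p of 17 alternatives ran from 0.429 to 1) and no list passed after adjustment. Without dnTCF4 2 the developmental difference turned to -0.056 and that of the beta-catenin/TCF targets to -0.26, and the Hox difference turned to 0.53 with windows of 1 kb.

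Most of the 21 genes listed here as tied to the study were unmarked at their ends, as were most protein-coding genes. A peak in any library was found for 4 of the 21, against 15.8% of all protein-coding genes. The list passed Fisher's exact test against other genes in no library. The 4 marked genes were Cdh1 and Gata3 (2 control and 1 dnTCF4 library each), Krt14 (1 of each) and Lef1 (1 control library). Fisher's exact test gave each of these 4 genes p = 1, as did the test adjusted over the list alone. Ezh2, Ccn6, Tcf7l2, Ctnnb1, Axin2, Tcf7, Cdkn2a, Hmga2, Igf2bp2, Igf1r, Bmp4, Trp63 and Esr1 had none. Among 25 growth suppressors only Trp73 was marked, in control 3. In the CCN family only Ccn3 was marked, in control 3.

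The amount of called H3K27me3 differed between the groups by less than the spread of libraries. The geometric mean was 4434 peaks in control and 2464 in dnTCF4 libraries, with SDs of 1.05 and 0.861 on the log10 scale (n = 4 each; difference -0.255, exact permutation p = 0.714). Covered length had geometric means of 3.02 and 1.53 Mb (n = 4 each, exact permutation p = 0.743) and median peak width 405 and 370 bp (n = 4 each, exact permutation p = 0.743). Marked genes made up 0.296%, 0.356%, 14.5% and 7.66% of all genes in control and 9.29%, 0.0925%, 2.83% and 1.07% in dnTCF4 libraries (n = 4 each, exact permutation p = 0.800). Without control 3 the difference in peak number turned to 0.107, and without dnTCF4 2 to 0.115. The X chromosome held 4.56 ± 3.53% of covered length in control and 1.41 ± 1.30% in dnTCF4 libraries (SD, n = 4 each, exact permutation p = 0.229). Peaks near gene ends made up 11.4 ± 2.50% of control and 14.0 ± 1.05% of dnTCF4 peaks (SD, n = 4 each, exact permutation p = 0.114). Without control 1 that difference was 3.77 percentage points (exact permutation p = 0.0286). Over 13 alternatives it ran from 0.810 to 3.77 percentage points, and 12 of them gave the same call as the main test.

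At least 1 library marked 3425 genes (15.8%), and 543 genes were marked in at least 2 libraries of each group, where libraries marking genes independently would give 1.07. Without control 3 that count was 103, without control 4 it was 106, without dnTCF4 1 it was 181 and without dnTCF4 3 it was 210. The 4 genes marked in all 8 libraries were Mmp7, Mmp8 and Cep126 on chromosome 9 and Nipal2 on chromosome 15 (34572796 to 34679207). Lalba, Krt73, Clgn, Emid1, Ttbk1 and Hoxc5 were marked in 7 libraries. Peaks covered on average 96.8% of the better covered end window of Mmp7 and 36.4% of that of Nipal2.

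Genes marked in at least 2 control libraries and 0 dnTCF4 libraries numbered 307, and 305 of these were marked in exactly control 3 and control 4, the longest control lists. The opposite set held 13 genes, all marked in dnTCF4 1. In control libraries Retn, an adipokine, and the chemokine receptor Cxcr1 were marked in 3 of 4 and in 0 of 4 dnTCF4 libraries. Lcn4, Krt26, Gm29735, Tas2r119, Tex28, 1700016D06Rik, 9330182O14Rik and Nr5a2 were marked in 2 and 0. Frmd5, on chromosome 2 from 121545529 to 121807087, was marked in 3 dnTCF4 and 0 control libraries. Avp, Alk, Dcaf17, Foxs1, Cryaa, Mcc, Cdpf1, Large2 and Nrxn2 were marked in 2 dnTCF4 and 0 control libraries. Of the 13 genes marked in dnTCF4 libraries only, 5 lay on chromosome 2, and of those marked in control libraries only, 10.4% lay on chromosome 8 and 10.7% on X, against 4.82% and 4.47% of all genes; chromosomes 2 and 8 as wholes also held different shares of covered length in the groups. By Fisher's exact test 0 genes had an adjusted p under 0.05 and 0 an unadjusted p under 0.05, the lowest being 0.143. The conditional exact test gave 30 genes at an unadjusted p under 0.05 and 0 after adjustment, with the lowest adjusted p for Frmd5 (0.125). That test was run in 1 setting. It is itself among the 18 alternatives to the main Fisher's exact test, whose lowest adjusted p ran from 0.125 to 1. Without control 3 or without control 4 the control set held 2 genes, and without dnTCF4 1 it held 1023. The dnTCF4 set held 79 genes without control 3, 1 without dnTCF4 1 and 3 without dnTCF4 3.

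Over the union of 61435 regions, 6044 were marked in at least 2 control and 0 dnTCF4 libraries and 133 the other way. The region at chromosome 6, 47648291 to 47648935, was marked in 4 control and 0 dnTCF4 libraries and lies 3.97 kb from Gm40369. Regions in Tsc22d3 (X, 140577217 to 140583489), Pgm5 (chromosome 19, 24779295 to 24784371) and Rorb (chromosome 19, 18992686 to 18996815) were marked in 3 and 0, and a region 66.7 kb from Stk3 (chromosome 15, 35222562 to 35226977) in 4 and 1. In the other direction, a region 0.825 kb from Frmd5 (chromosome 2, 121807912 to 121810292), a region in Mettl7a1 (chromosome 15, 100305839 to 100307152) and a region 33.2 kb from Fam210b (chromosome 2, 172311120 to 172312404) were marked in 0 control and 3 dnTCF4 libraries. A region inside Epcam (chromosome 17, 87641393 to 87642059) and a region 0.111 kb from Galnt9 (chromosome 5, 110543061 to 110543921) were marked in 1 control and 4 dnTCF4 libraries. No single region was tested. Without control 3 the control set held 29 regions and the dnTCF4 set 600, without control 4 they held 37 and 203, and without dnTCF4 1 they held 11999 and 10. Without dnTCF4 3 the dnTCF4 set held 35. With lists of equal length the control set held 24 regions and the dnTCF4 set 42, so the excess in the control direction was not kept.

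Over the 28 pairs of libraries, the list of larger covered length overlapped between 38.3% (control 1 in control 2) and 99.0% (dnTCF4 2 in dnTCF4 1) of the peaks of the other. Control 3 overlapped 97.9% of the peaks of control 1, 98.4% of those of dnTCF4 2 and 94.8% of those of dnTCF4 4. Among other pairs, dnTCF4 1 overlapped 90.6% of the peaks of control 1 and 48.1% of those of control 4, and dnTCF4 4 overlapped 52.8% of those of control 1. The Jaccard index averaged 0.0835 within groups and 0.105 between them (12 and 16 pairs, difference -0.0220, one-sided exact permutation p = 0.686). This index cannot exceed the ratio of the covered lengths of a pair, and covered lengths ranged 408-fold. Control 1 and control 3 had an index of 0.0045, although 98.0% of the covered length of control 1 was shared. The Jaccard test therefore says little of whether groups resemble each other. The overlap coefficient averaged 0.846 within and 0.750 between groups (difference 0.0952, one-sided exact permutation p = 0.0286, the smallest these 70 assignments give). It too varied with covered length, at 0.980 for control 1 and control 3, whose lengths lie far apart. Pairs of closer length had 0.461 (control 1 and control 2) and 0.426 (control 4 and dnTCF4 1). The coefficient was not computed with lists of equal length, so its test cannot tell group resemblance from list length. The Jaccard difference turned to 0.0179 with lists of equal length (one-sided exact permutation p = 0.143) and to 0.0225 with the 5 libraries of at least 1000 peaks (one-sided exact permutation p = 0.2).

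A block of chromosome 9 around the matrix metalloproteinase genes held the most significant peak of every list. Between 62 and 108 peaks per library lay there, from 7283822 in control 3 to 8231118 in dnTCF4 1. They made up 66.9% of covered length in dnTCF4 2 and 0.583% in control 3. The median fold enrichment in the block was 1.46 in control 3 and 2.04 in dnTCF4 2, below the 3.01 and 4.99 of other peaks in those lists. Peaks covered the ends of Mmp7, Mmp8 and Cep126 in all libraries. The ends of Tmem123, Birc2, Birc3 and Yap1 carried no peak in any library. Covered length in the block differed between the groups by less than the spread of libraries (n = 4 each, difference -0.0400 on the log10 scale, exact permutation p = 0.771).

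**Figure D3:**
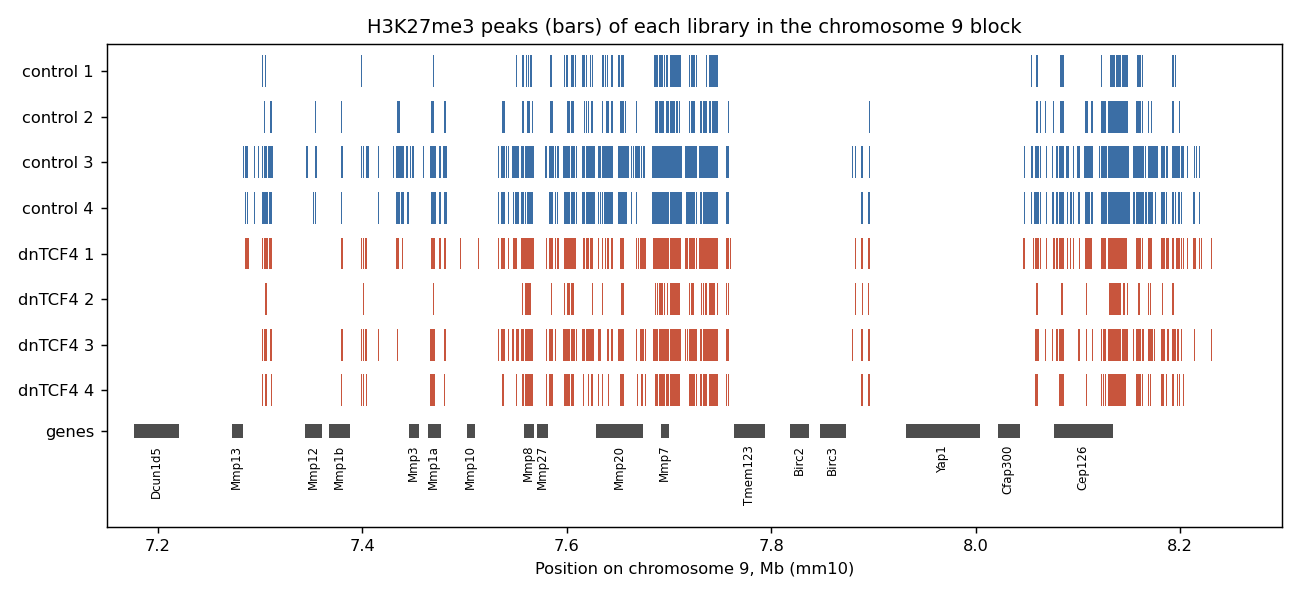
Peaks of each library (bars, control blue and dnTCF4 red) and annotated genes (grey) along chromosome 9, with position in Mb. Peaks lie at Mmp8, Mmp7 and Cep126 in all 8 libraries, and cover at most 2.51% of the stretch from Tmem123 to Yap1.

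Marked sequence was spread unevenly over the chromosomes, a comparison chosen after the data were seen. Outside the chromosome 9 block, chromosome 2 held 13.8 ± 1.72% of covered length in control and 26.2 ± 5.08% in dnTCF4 libraries (SD, n = 4 each), and every dnTCF4 library lay above every control library. Chromosome 8 held 6.77 ± 0.673% and 2.86 ± 0.465% (SD, n = 4 each), and every dnTCF4 library lay below every control library. The two-sided exact permutation p was 0.0286 for each, the smallest possible, with an adjusted p of 0.286 over 20 chromosomes. At least 12 of 20 chromosomes would need that smallest p for any to pass the adjustment. With the block included, p was 0.143 for chromosome 2 and 0.0571 for chromosome 8 (exact permutation test). Of the regions marked in dnTCF4 libraries only, 36.1% lay on chromosome 2, against 12.4% of all regions and 10.3% of those marked in control libraries only. Of the regions marked in control libraries only, 10.6% lay on chromosome 8 and 11.6% on X, against 6.13% and 8.40% of all regions. These shares were not tested.

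**Figure D4:**
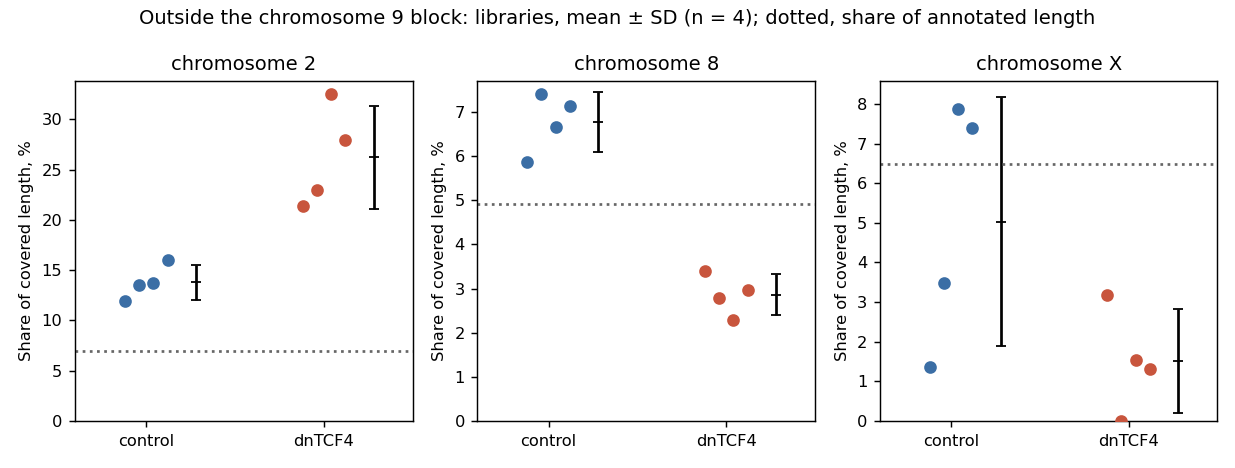
Share of covered length outside the chromosome 9 block, in percent, on chromosomes 2, 8 and X for control (blue) and dnTCF4 (red) libraries; points are libraries, bars the mean and 1 SD (n = 4) and dotted lines the share of annotated length. The groups are apart on chromosomes 2 (13.8% and 26.2%) and 8 (6.77% and 2.86%) and overlap on X (5.03% and 1.51%).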

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

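The tests of explanations in this part, list length, splits and the chromosome 9 background, were written down after the results were seen. In groups of 4 libraries, 94 sets of values were checked for a library far from the rest, and 3 were found, where chance flags about 1 in 20 groups. The log2 odds ratio of the epithelial genes was 4.11 in dnTCF4 2, against 3.03 to 3.20 in the other dnTCF4 libraries, and that of the basal and myoepithelial genes was 4.55, against 0.81 to 1.26. Both come from a library with no marked member of either list, where the ratio rests on the added 0.5. Chromosome 16 held 4.14% of covered length outside the chromosome 9 block in dnTCF4 1, against 2.87% to 3.07% in the other dnTCF4 libraries.

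The first pattern weighed is the excess of genes marked in control libraries only, 307 against 13. With each list reduced to its 191 highest peaks the sets held 5 and 6 genes, a ratio of 0.833, so the length of the peak lists may account for the excess, and an effect of dnTCF4 on single genes stays open. Of the 35 splits of the 8 libraries, 24 gave at least as many genes in both directions together as the real 320, and the highest other split gave 1882, so chance cannot be excluded. For regions 11 of 35 splits gave at least the real 6177, with 19777 as the highest other. These highest splits set control 1, control 2, dnTCF4 2 and dnTCF4 4, the shortest lists, against the rest. The rule of 2 against 0 libraries gives high counts where long lists face short ones. List length thus shapes the split counts, so they cannot decide on chance or on an effect of dnTCF4.

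The second pattern is the chromosome 9 block. An estimate of the background behind each peak, solved from the deposited fold and p under the Poisson model of MACS2, was at least 45.0 times as high in the block as at other peaks in every library, and at least 32.6 times for the lowest twentieth of block peaks. This restates the low fold and high significance by which the block was found, and at most 3 other peaks per list had folds as low, so a raised background over the block, as extra copies of the interval could give, and a few repeated stretches cannot be told apart. Peaks were listed there in all 4 control libraries, which argues against dnTCF4 as the origin of the block. Copy number was not measured, and the estimate depends on a model whose options are not given in the sources used here.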

How the results depend on the processing

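Alternatives marked as added were chosen after seeing the data. None gave a gene list or a gene an adjusted p under 0.05, over 17 alternatives for lists (lowest adjusted p from 0.429 to 1) and 18 for genes, which says little of stability, since with 4 libraries against 4 at least 12 of 20 lists must reach the smallest p for any to pass. The X share kept its direction in 14 of 14 alternatives, from -5.68 to -0.281 percentage points. Leaving out 1 library moved the log10 difference in peaks from -0.594 to 0.115, in covered length from -0.661 to 0.118, in width from -0.0825 to 0.0174 and in marked genes from -0.452 to 0.215. It moved the share of peaks near gene ends from 1.87 to 3.77, the log2 odds ratio difference of developmental factors from -0.056 to 0.71 and of beta-catenin/TCF targets from -0.26 to 1.21. It moved genes marked in control only from 2 to 1023, in dnTCF4 only from 1 to 79 and in both from 103 to 543, and regions from 29 to 11999 and from 10 to 600. For genes marked in control only, dnTCF4 only and both, lists of equal length gave 5, 6 and 15, and windows covered to 50% gave 33, 1 and 14. A rule of 3 libraries gave 2 and 1, and libraries with at least 1000 peaks, each reduced to 1838 (added), gave 10 and 64. These were 2 control and 3 dnTCF4 libraries. The rule thus asked for a peak in both control libraries but in only 2 of 3 dnTCF4 libraries, which favours the dnTCF4 set. Shared genes numbered 348 under the stricter minimum, 281 and 1000 with windows of 1 kb and 5 kb, and 1085 with whole genes (added). Regions in control only numbered 3839 under the stricter minimum and 24 with equal lengths, and in dnTCF4 only 42 with equal lengths and 61 with 10 kb bins. The Hox difference turned to 0.53 with 1 kb windows, 0.53 with libraries of at least 1000 peaks and 0.39 with observed over expected members (added). The developmental one turned to -0.11 with 1 kb windows and -0.61 with windows covered to 50%. With equal lengths the epithelial difference turned to -0.031, that of beta-catenin/TCF targets to -0.032 and that of marked genes to 0.00945. The similarity difference turned to 0.0179 with equal lengths, 0.0225 with libraries of at least 1000 peaks and 0.0952 with the overlap coefficient. That coefficient, not computed with lists of equal length, gave 0.128 outside the chromosome 9 block (added, one-sided exact permutation p = 0.0286). The cause was not tested, beyond fewer peaks or libraries where these were reduced. Taking same-numbered libraries as a replicate block gave differences of -0.255 for log10 peaks (exact sign-flip p = 0.875, smallest possible 0.125), moved genes marked in dnTCF4 only to 22 and regions to 217, and changed no call. Gene marks, centred within each group, correlated at -0.661, 0.646, -0.103 and -0.325 between same-numbered libraries. List length bears on these values: control 1 had 426 peaks and dnTCF4 1 had 21492, control 2 had 738 and dnTCF4 2 had 191. They therefore cannot tell whether the numbers pair libraries.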

Other observations

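The tests of chromosomes 2 and 8 in this part were chosen after the results were seen. Outside the chromosome 9 block, chromosome 15 held 25.0 ± 13.8% of covered length in control and 22.1 ± 5.45% in dnTCF4 libraries (SD, n = 4 each), where it makes up 3.95% of annotated length. Chromosome 17 held 10.9 ± 6.08% and 12.7 ± 7.66% (SD, n = 4 each), against 3.61% of annotated length. Chromosome 12 held 0.343 ± 0.416% and 0.296 ± 0.337% (SD, n = 4 each), against 4.56%. Of genes of other cell types, 19 of 34 neuronal genes were marked in control 3, 6 in control 4 and 8 in dnTCF4 1, with Slc32a1 marked in 2 control and 3 dnTCF4 libraries. Leukocyte genes had 8 of 22 marked in control 3, among them Cd3e, 1 in control 4 and 2 in dnTCF4 1. Endothelial genes had 6 of 16 marked in control 3, and Kdr, a receptor of vascular growth factors, was marked in 3 libraries of each group. Cartilage, bone and muscle genes had 6 of 24 marked in control 3 and in dnTCF4 1, and Sp7, a transcription factor of bone formation, was marked in 2 control and 4 dnTCF4 libraries. Of 11 adipocyte genes, 1, 0, 3 and 1 were marked in the control libraries and 0 in each dnTCF4 library, and the list passed the test in no library and not between the groups (exact permutation p = 0.543). BMP, activin and TGF-beta genes had 6 of 27 marked in control 3 and 4 in dnTCF4 1, among them Bmp2, marked in 2 control and 3 dnTCF4 libraries. By Fisher's exact test against other genes, the neuronal and leukocyte lists were over-represented in 1 library each. The endothelial list, the cartilage, bone and muscle list and the BMP, activin and TGF-beta list passed in 0.

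The third pattern weighed is the larger share of chromosome 2 and the smaller share of chromosome 8 in covered length of the dnTCF4 libraries. Different numbers of listed peaks are argued against as the whole cause. With 129 peaks per list outside the block the shares were 14.6 ± 1.08% and 24.9 ± 3.29% on chromosome 2. On chromosome 8 they were 10.2 ± 4.13% and 3.20 ± 0.537% (SD, n = 4 each, exact permutation p = 0.0286 for each chromosome). Both chromosomes were chosen on these same lists, so these p-values are not independent support. Equal numbers of peaks do not equalise sequencing depth, whose part stays open. A few loci are argued against on chromosome 8, where 100% of the 10 Mb bins (13 of 13) held a smaller mean share in dnTCF4 libraries. The 2 bins of largest difference held 40.8% of the difference there, and the groups stayed apart without them (exact permutation p = 0.0286). A few loci stay open on chromosome 2, where 78.9% of bins (15 of 19) went in its direction. Its bins from 150 to 170 Mb also held 40.8% of the difference, but the groups overlapped without them (exact permutation p = 0.0857). Of the 35 splits, 4 set at least as many chromosomes fully apart as the real 2, and the highest other split gave 8. That split set control 1, control 2, dnTCF4 2 and dnTCF4 3 against the rest. The splits used lists of full length, where short lists can lack a chromosome, as dnTCF4 2 did chromosome 1. List length may thus shape these counts, so they cannot decide on chance, which is not excluded. A difference in chromosome copies between the transduced populations may also account for the pattern, as may an effect of dnTCF4, and neither was tested.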
